A study of Mus musculus with 8 samples.

How the data were processed

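The series holds 8 RNA-seq libraries of mouse splenic B cells in 4 groups of 2 libraries. The values are log2 values as deposited by the authors in 1 table of 15681 genes, and range from -5.23 to 14.51. Read from the values, each is the log2 of (estimated reads + 0.5) in RPM of an effective library size that differs from the library's total; the labels do not name the tool that made it. Per the submitters' processing notes, CASAVA 1.8, cutadapt and RSEM 1.2.3 were used with the genome build GRCm38; their order and parameters, the annotation, the strand setting and any filter on genes are not given in the sources used here. The lowest value of each library was taken as 0 reads, which made all other values multiples of 0.01 read within a tolerance of 0.0002 read, and from this the estimated reads were recovered. Totals were 17.54 and 17.2 M estimated reads in the control libraries, 17.91 and 17.68 M in Max_KO, 17.55 and 14.88 M in those labelled Myc_KO, and 17.89 M in each of those labelled double_KO. Total divided by effective size was 1.092 and 1.043 in the controls and 0.956 to 0.995 in the knock-out libraries.

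Groups were taken from the description and genotype fields. For 2 libraries, labelled Myc_KO replicate 1 and double_KO replicate 2, the title gives the other of these genotypes, as does the column name of the deposited values. Both readings were fitted. Gene symbols and coordinates came from the GENCODE vM21 annotation of GRCm38 matched by gene identifier; 15622 genes had a symbol and 59 had none. Reads of near-identical genes are divided by RSEM's estimate, and the effective size makes every change relative to the bulk of the genes of a library, not to the cell.

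The design assumed a normalized value to be put on the log2(value + 1) scale; since the values were already log2 values, they were used as they are. A count test was not run, because the estimated reads are not whole. Genes at 1 RPM or more in at least 2 libraries were kept, which left 12467. All 8 libraries were fitted in 1 model of the 4 groups with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend), with 4 residual degrees of freedom and 4.2 prior degrees of freedom. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Comparisons were each knock-out group with the control, the knock-out groups with each other, and the interaction (double_KO minus Myc_KO minus Max_KO plus control). Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 recovered the reads and drew the figures.

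The 27 gene lists, with 465 entries of which 400 were tested, were written from textbook knowledge. The 24 lists with at least 5 tested members were tested with camera, with a preset correlation of 0.01 between genes, beside an estimated correlation and beside fry, and adjusted over the lists of a comparison. Members past the threshold were counted over all genes and adjusted over the list alone. Overlaps between comparisons were set beside those of independent lists and beside 50 draws of unchanged groups simulated against the same 2 controls. After seeing the data, overlaps were also counted with a different control library for each of the 2 groups, and the interaction was set beside 50 draws simulated with additive changes.

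Genes named in the text followed a rule. First come the members of the Myc and Max network. Then, for each comparison with the control, come the 8 highest and 8 lowest log2 changes among called genes whose libraries did not overlap between the groups and whose mean was at least 5 RPM in 1 of them, leaving out predicted genes, receptor segments and genes without a symbol. For each list, up to 3 called members with the lowest adjusted p follow, and for comparisons between knock-outs and the interaction the 5 highest and 5 lowest. The text gives part of these, and some genes that met the rule are not reported here. For the interaction, which compares no 2 groups, the condition on overlap was dropped and the level was asked of any of the 4 groups; this reading was chosen after the first fit. The rule was also applied to the groups from the titles. Thy1, and the genes of the closing section outside this rule, were chosen after their values were seen.

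A group at 0 reads was set at a floor of 3 reads over the group, and with 1 to 3 reads the ratio of reads is given with an exact 95% interval. Groups, tests, lists, the rule for named genes and a set of alternatives were fixed before the data were examined. These alternatives were other pseudocounts and filters, median-of-ratios, quantile and same-total scaling, a replicate block, groups from the titles, the libraries without the 2 disputed ones, only the groups compared, each library left out, other eBayes settings and stricter thresholds. Voom weights, a pseudocount of 1 on the linear values, the number series of the titles as a term or as a subset, and pooling of all libraries with a Myc loss were added after seeing the data. The replicate numbers did not clearly pair the libraries by the check used, the correlation over all genes of deviations from group means. It was -0.1, 0.09 and 0.03 between the control and Max_KO, Myc_KO and double_KO. Between Max_KO and Myc_KO it was 0.07, between Max_KO and double_KO 0.11, and between Myc_KO and double_KO 0.26. The check does not exclude a shift shared by some genes. On simulated data with 100 genes changed by a log2 of 1 and 100 by a log2 of 2 among 12467, the fit recovered 72% and 84% for Myc_KO, 71% and 82% for Max_KO, and 76% and 85% for double_KO, with 9, 12 and 11 false calls.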

Results

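Transcripts of activated B lymphocytes were measured by RNA sequencing in mice lacking Myc, Max or both. Myc is a transcription factor that binds DNA as a dimer with Max. Mature B cells sorted from the spleens of mice aged 8 to 10 weeks were stimulated in culture with 20 µg/ml lipopolysaccharide and 20 ng/ml interleukin 4, a combination that activates B cells and induces class switching, and were harvested at 72 h. The 4 groups were heterozygous controls (control), Myc-deficient cells (Myc_KO), Max-deficient cells (Max_KO) and cells deficient in both (double_KO), with 2 libraries in each. The table held 15681 genes, of which 12467 were tested. Libraries held 14.88 to 17.91 M estimated reads. Levels below are in RPM, estimated reads scaled to the effective library size, and errors of levels are SD over the 2 libraries of a group. The labels do not say whether the libraries of a group came from separate mice, so that p-values measure only the spread between these libraries. Transcripts encoded by mitochondrial DNA made up 5.69% and 4.93% of the reads in the control libraries and 2.21% to 2.96% in the 6 knock-out libraries.

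Myc (ENSMUSG00000022346, GRCm38 chromosome 15, 61985391 to 61990374) was at 111 and 116 RPM in the control libraries. It was at 38.8 and 48.3 in the libraries labelled Myc_KO replicates 1 and 2, at 55.4 and 55.8 in those labelled double_KO, and at 192 and 176 in Max_KO. Max (ENSMUSG00000059436, GRCm38 chromosome 12, 76937269 to 76962201) was at 55 and 54.5 in the control libraries and at 16.4 and 15.5 in Max_KO. In the library labelled Myc_KO replicate 1, Max was at 28.6, below both control libraries, and in the library labelled Myc_KO replicate 2 it was at 70.5. In the libraries labelled double_KO, Max was at 31.2 in replicate 1 and at 59.8, above both control libraries, in replicate 2. For these 2 libraries, labelled Myc_KO replicate 1 and double_KO replicate 2, the sample title gives the other of the 2 genotypes. The description and the genotype field give the one used here, while the columns of the deposited values carry the names of the titles. The level of Max goes against the description in both. Counts of called genes are therefore given below also for groups taken from the titles and for the 6 undisputed libraries. Estimated reads over the whole gene do not tell a shortened transcript from an intact one, so that the remaining Myc and Max reads do not measure intact transcripts.

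**Figure D1:**
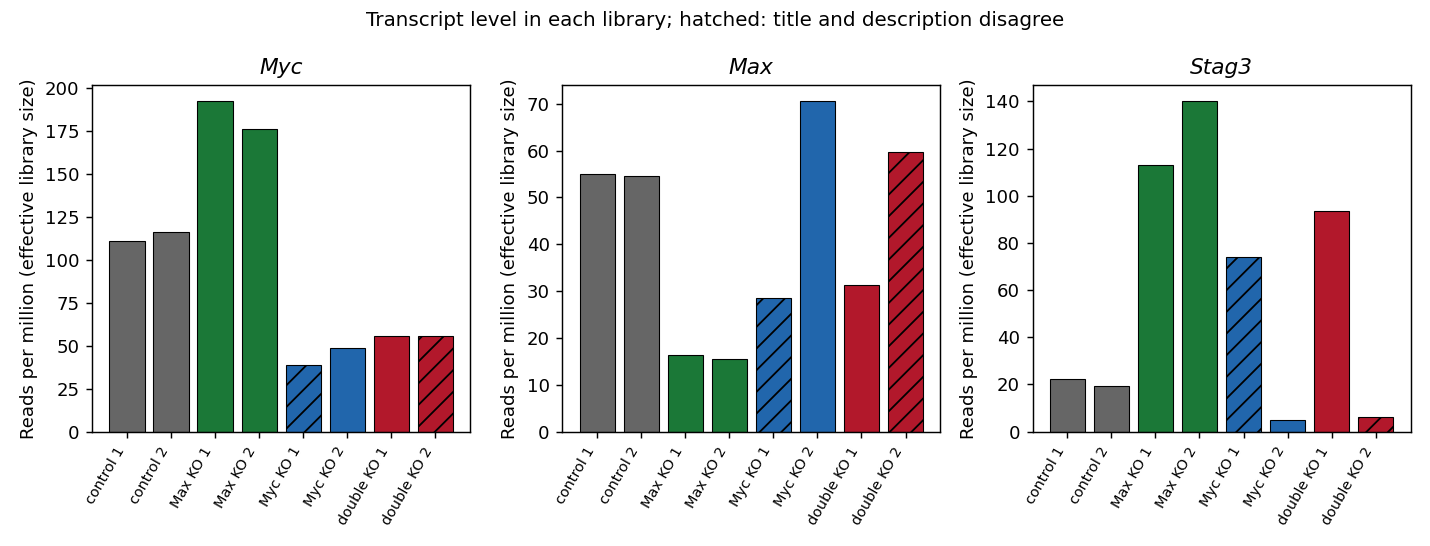
Levels of Myc, Max and Stag3 in each of the 8 libraries, in RPM of the effective library size; each bar is 1 library and hatched bars are the 2 libraries whose title and description differ. Max stood at 28.6 in the library labelled Myc_KO replicate 1 and at 59.8 in that labelled double_KO replicate 2, against 55 and 54.5 in the control libraries.

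Other members of the Myc and Max network also moved. Mga, a Max-binding repressor, rose in all 3 knock-out groups, from 67.4 ± 4.45 RPM in the controls to 163 ± 30.8 in Myc_KO, 194 ± 23.2 in Max_KO and 168 ± 45.1 in double_KO, with limma log2 changes of 1.26, 1.52 and 1.29 (SE 0.196 each; adjusted p = 0.00181, 0.00104 and 0.00171). By library, Mga was at 185 and 141 in those labelled Myc_KO replicates 1 and 2. It was at 200 and 136 in those labelled double_KO replicates 1 and 2, and at 178 and 210 in Max_KO. Under the titles the lower values, 141 and 136, are both of Myc_KO. Mxd1, which dimerises with Max as an antagonist of Myc, fell from 37.8 ± 0.127 to 14.6 ± 1.34, 11.4 ± 3.16 and 16.8 ± 0.651. Mxi1, of the same family, fell in Myc_KO (log2 change -1.74 ± 0.348) and double_KO (-1.99 ± 0.348) and was at -1.01 ± 0.348 in Max_KO (limma adjusted p = 0.0507, with 0.00634 to 0.261 over the alternatives). Mnt, another Max partner, rose in Max_KO from 25.5 ± 4.35 to 85.1 ± 8.25 (limma adjusted p = 0.0227), a call lost without any 1 of control replicate 1, control replicate 2, Max_KO replicate 1 or Max_KO replicate 2 (adjusted p = 0.125, 0.069, 0.0621 and 0.104), with adjusted p from 0.000348 to 0.125 over all alternatives. In the disputed libraries Mnt was at 67.7 in that labelled Myc_KO replicate 1, against 22.8 in Myc_KO replicate 2, and at 38.1 in that labelled double_KO replicate 2, against 78.2 in double_KO replicate 1. Of the 11 tested members of the network list, 3 rose and 3 fell in Myc_KO, 4 rose and 2 fell in Max_KO, and 2 rose and 3 fell in double_KO. Adjusted over the list alone, the numbers were the same except that 3 fell in Max_KO. Of the 3 genes that rose in Myc_KO, Mlx and Mlxip lost their calls without control replicate 1 (limma adjusted p = 0.161 and 0.154), control replicate 2 (0.173 and 0.0936) and Myc_KO replicate 2 (0.139 and 0.144), and Mlx also without the library labelled Myc_KO replicate 1 (0.125), double_KO replicate 1 (0.0671) and the library labelled double_KO replicate 2 (0.0667), with 0.0108 to 0.321 for Mlx and 0.00173 to 0.154 for Mlxip over the alternatives. In Max_KO, Mlxip lost its call without control replicate 1, control replicate 2 and Max_KO replicate 2 (adjusted p = 0.157, 0.096 and 0.167, with 0.00739 to 0.184). Camera did not call the list in any of the 3 groups (adjusted p = 0.473, 0.549 and 0.605 with the preset correlation). For Mycl, Mxd3 and Mxd4 no change passed the threshold in any of the 3 groups.

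In Myc_KO against control, the genes with the largest rises included Met, which encodes the hepatocyte growth factor receptor, and the granzyme Gzmb, a protease of cytotoxic lymphocytes. Gzmb was at 90.2 ± 51.5 RPM against 1.73 ± 0.683 in the controls (49.8-fold, log2 change 5.64 ± 0.469). Iigp1, an interferon-induced GTPase, was at 28 ± 5.37 against 1.25 ± 1.11 (28.5-fold). The lowest was Muc2, a secreted mucin, with no read in either Myc_KO library, which puts it at least 66.3-fold lower than in the controls when 3 reads over the group are taken as the floor. Rnf183 fell 31.9-fold, from 20.7 ± 0.0525 to 0.655 ± 0.141, and Sphk1, a sphingosine kinase, 25.5-fold, from 10.2 ± 1.34 to 0.459 ± 0.324. For Met, with 1 read in the controls together, the ratio of reads was 248 (95% interval 44.1 to 9830), and for Gfi1b, a transcriptional repressor with 3 control reads, it was 93.1 (31.5 to 454). These intervals and floors cover counting error only. The log2 change of Met ranged from 5.83 to 7.77, and that of Gfi1b from 5.67 to 6.61, with 1 library left out in turn. With 1 library left out the log2 change was 3.77 and 5.89 for Iigp1 without control replicates 1 and 2, 6.26 and 5.02 for Gzmb, and -5.46 and -3.88 for Sphk1, without Myc_KO replicates 1 and 2. Each of these genes was higher, or lower, in both Myc_KO libraries than in both control libraries, which the rule that chose them required.

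Limma with Benjamini-Hochberg adjustment called 5098 genes between Myc_KO and control, 2780 higher and 2318 lower, of which 1762 changed at least 2-fold. When each library was scaled to the same total instead, 67.3% of the called genes were higher, against 54.5% with the deposited scaling, and the median change of all genes moved from 0.01 to 0.14. Without control replicate 1 the number was 2662, and without control replicate 2 it was 3088. Grouping by title gave 2993 higher and 2660 lower, with 4536 of the 5098 genes among them, and the undisputed libraries gave 2370 and 2069.

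In Max_KO against control, Max fell from 54.7 ± 0.36 to 16 ± 0.647 RPM (3.43-fold, log2 change -1.78 ± 0.407) and Myc rose from 114 ± 3.54 to 184 ± 11.2 (1.61-fold, log2 change 0.69 ± 0.117). Met, Iigp1 and Gzmb were again among the genes with the largest rises, Iigp1 at 41.8 ± 18.6 (40.8-fold) and Gzmb at 39.5 ± 20.2 (22.2-fold), together with the guidance factor gene Slit3 (13.8-fold, from 0.581 ± 0.25 to 7.66 ± 0.601). For Met the ratio of reads was 238 (42.4 to 9450), and its log2 change ranged from 6.3 to 7.85 with 1 library left out in turn. The log2 change of Iigp1 was 4.29 without control replicate 1 and 6.41 without control replicate 2, against 5.35. Trim12a (ENSMUSG00000066258, GRCm38 chromosome 7, 104299894 to 104315466) fell 55.9-fold, from 37.8 ± 18.1 to 0.665 ± 0.278, and Trim30d (ENSMUSG00000057596, chromosome 7, 104470014 to 104507849) 39.3-fold, from 26.4 ± 8.16 to 0.662 ± 0.138. The metallothioneins Mt2 and Mt1 fell 19.6-fold and 12.3-fold, and the mucin Muc1 fell 17.3-fold, from 7.22 ± 0.214 to 0.418 ± 0.00162. The Trim genes of chromosome 7, the granzymes and the metallothioneins have close copies in the genome, so that the split of reads among copies is uncertain.

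For Max the limma adjusted p was 0.0107; it was 0.063 without control replicate 1, 0.056 without control replicate 2 and 0.0565 without Max_KO replicate 2, with a range of 8.58e-05 to 0.063 over the alternatives. Limma called 4745 genes between Max_KO and control, 2675 higher and 2070 lower, of which 1486 changed at least 2-fold. Scaled to the same total, 67.5% of the called genes were higher, against 56.4%, and the median of all genes moved from 0.02 to 0.13. The number was 2250 without control replicate 1, 2758 without control replicate 2 and 2924 without Max_KO replicate 2. The sample titles carry numbers in the 30s or the 40s; the labels do not call these batches. With the number series as a term in the model the number was 2920, and within the 30s series it was 2916. Titles gave 2785 higher and 2165 lower genes, and the undisputed libraries 2759 and 2238.

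In double_KO against control, Gzmb rose 46.6-fold, from 1.73 ± 0.683 to 77.2 ± 3.57 RPM. Rsad2, an interferon-induced antiviral gene, rose 20.6-fold, from 0.551 ± 0.207 to 11 ± 0.0298. Mylk, a myosin kinase gene, fell 39.9-fold, from 6.39 ± 0.248 to 0.163 ± 0.0412, Rnf183 fell 38.6-fold to 0.543 ± 0.125, and Egln3, an oxygen-dependent hydroxylase, fell 25-fold, from 65.1 ± 6.85 to 2.8 ± 1.51. Without the library labelled double_KO replicate 2 the log2 change of Egln3 was -4.07, against -4.65. The ratio of reads was 243 (43.3 to 9640) for Met and 66.7 (22.5 to 326) for Gfi1b. With 1 library left out in turn, their log2 changes ranged from 6.32 to 7.87 and from 4.68 to 6.28. Max was at 45.5 ± 20.2 against 54.7 ± 0.36 in the controls (log2 change -0.34 ± 0.407, limma adjusted p = 0.526), and under the titles its log2 change was -0.87 (adjusted p = 0.000956, with 0.000766 to 0.876 over the alternatives).

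Limma called 5265 genes between double_KO and control, 2912 higher and 2353 lower, of which 1844 changed at least 2-fold. Scaled to the same total, 68.7% of the called genes were higher, against 55.3%, and the median of all genes moved from 0.02 to 0.16. The number was 2753 without control replicate 1, 3221 without control replicate 2 and 3157 without the library labelled double_KO replicate 2. Both libraries labelled double_KO carry numbers in the 40s and both control libraries numbers in the 30s, and with the number series as a term 334 genes were called. Those labelled Myc_KO also carry numbers in the 30s, so that only the Max_KO libraries inform the term. The lower number therefore does not tell an effect of the series from a less precise comparison. Titles gave 2727 higher and 2088 lower genes, with 4310 of the 5265 among them, and the undisputed libraries 2098 and 1493.

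All 30 cytosolic ribosomal protein genes fell in each group, with median log2 changes of -1.09 in Myc_KO, -0.92 in Max_KO and -1.11 in double_KO; Rpl28 went from 2140 ± 154 RPM to 796 ± 30.5, 889 ± 61.3 and 797 ± 90.9. All 13 transcripts encoded by mitochondrial DNA fell in each group (medians -1.22, -0.93 and -1.3), among them mt-Co2, a subunit of cytochrome oxidase, from 5490 ± 1090 to 2050 ± 96.2 in Myc_KO. Of the 16 glycolysis genes, 14 fell in Myc_KO, 4 in Max_KO and 15 in double_KO (medians -1.57, -0.96 and -1.63). With the replicate number as a block, 15, 14 and 15 fell, so that the lower number in Max_KO depended on the model. Gapdh went from 6050 ± 456 to 1940 ± 528, 2710 ± 565 and 1970 ± 715; of the 4 calls in Max_KO, those of Gapdh, Aldoa and Gpi1 were each lost without control replicate 1 (limma adjusted p = 0.081, 0.0614 and 0.0729), without control replicate 2 (0.0514, 0.0522 and 0.0588) and without Max_KO replicate 2 (0.0888, 0.0697 and 0.0863). Over the alternatives their adjusted p ranged from 0.000619 to 0.0888, from 0.000896 to 0.104 and from 0.000705 to 0.0866. Of the 18 cholesterol synthesis genes, 12, 9 and 12 fell and 0, 0 and 1 rose (medians -0.65, -0.5 and -0.77), and Fdft1, which makes squalene, went from 97.9 ± 0.313 to 47.6 ± 1.2, 53.1 ± 0.725 and 46.5 ± 5.24. Of the 18 genes of mitochondrial respiration and biogenesis, 6, 8 and 7 fell and 1 rose in each group (medians -0.24, -0.33 and -0.21), with Cox4i1 at 435 ± 15.4 in the controls and 233 ± 7.69, 227 ± 17.9 and 246 ± 4.72 in the knock-out groups.

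Adjusted over the list alone, the numbers that fell were the same for ribosomal proteins and mitochondrial transcripts. They were 15, 4 and 15 for glycolysis, 12, 12 and 12 for cholesterol synthesis with 1 gene rising in each group, and 6, 10 and 7 for mitochondrial respiration. Camera with the preset correlation called the ribosomal proteins lower (adjusted p = 1.59e-17, 1.7e-16 and 1.02e-17 in Myc_KO, Max_KO and double_KO; adjusted p = 0.74, 0.66 and 0.831 with an estimated correlation), and likewise the mitochondrial transcripts (2.38e-07, 4.53e-06 and 7.97e-08; adjusted p = 0.74, 0.66 and 0.831 with an estimated correlation). It called glycolysis (1.6e-05, 0.00168 and 2.02e-05; adjusted p = 0.74, 0.66 and 0.888 with an estimated correlation) and cholesterol synthesis (7.21e-05, 0.00255 and 0.000104; adjusted p = 0.74, 0.66 and 0.831 with an estimated correlation). It also called mitochondrial respiration (0.042, 0.003 and 0.0123; adjusted p = 0.74, 0.66 and 0.906 with an estimated correlation), a call lost in double_KO with the undisputed libraries (adjusted p = 0.0502). No list was called in any comparison with an estimated correlation. Fry called the ribosomal proteins and mitochondrial transcripts lower in each group, cholesterol synthesis in Myc_KO and double_KO, and glycolysis in none. The size of the ribosomal change depended on scaling: after quantile normalization the medians were -0.43, -0.35 and -0.47, with 26, 19 and 26 genes lower, and the mitochondrial transcripts had 10, 6 and 10 genes lower.

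**Figure D2:**
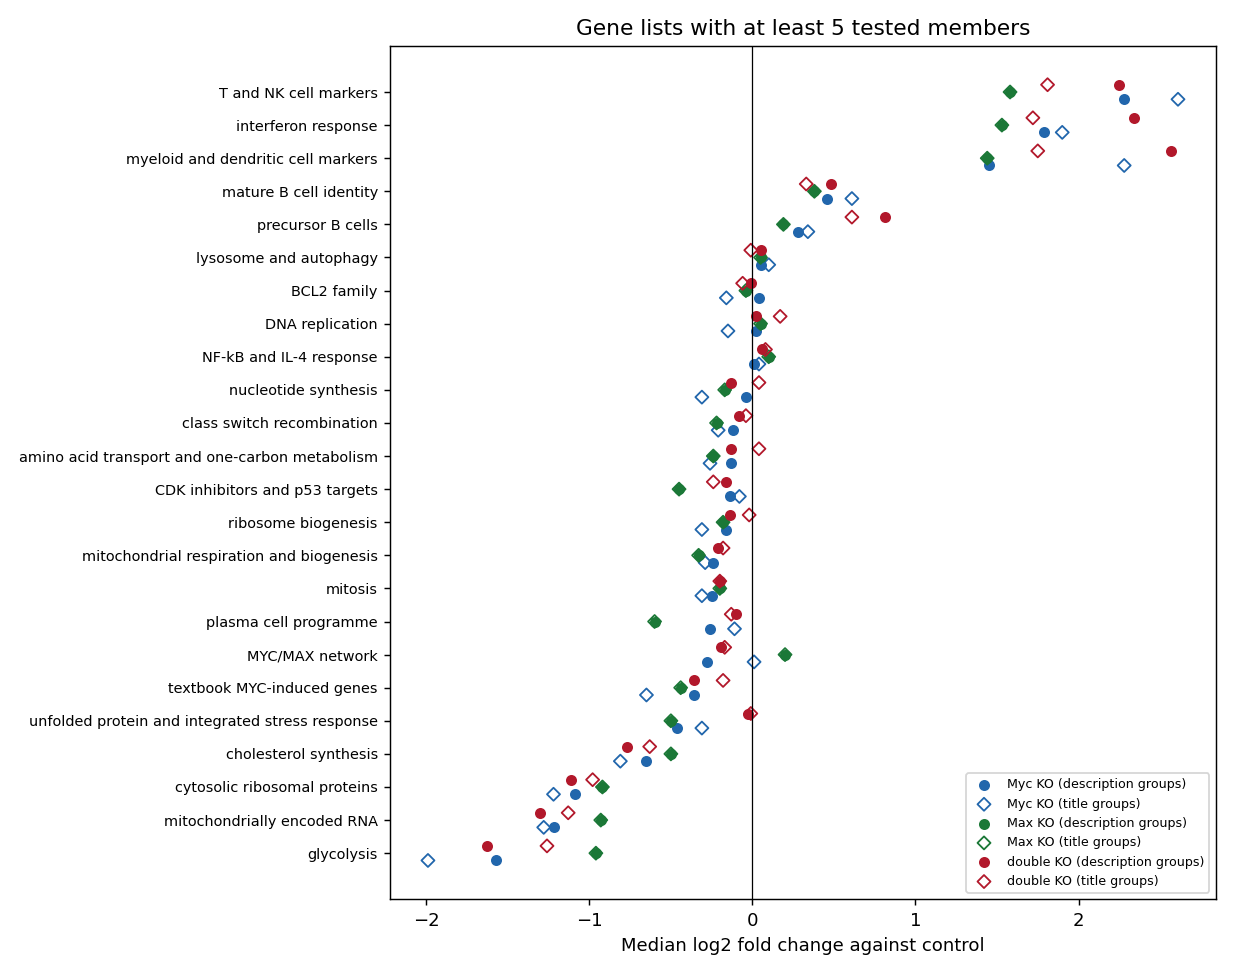
Median log2 fold change against control of the 24 gene lists with at least 5 tested members, for Myc_KO (blue), Max_KO (green) and double_KO (red); filled circles use the groups of the descriptions and open diamonds those of the titles. The medians of the ribosomal proteins lay at -1.09, -0.92 and -1.11 and those of the interferon response at 1.79, 1.53 and 2.34.

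Textbook Myc-induced genes moved less uniformly. Of the 22 genes, 9 fell in Myc_KO, 9 in Max_KO and 8 in double_KO (medians -0.36, -0.44 and -0.36), with the same numbers adjusted over the list alone. Nop56, a nucleolar protein gene, went from 371 ± 41.2 RPM to 210 ± 30.8, 207 ± 7.15 and 218 ± 37.6. The 1 gene of the list that rose in each group was Ccnd2, which encodes cyclin D2, from 559 ± 27.9 to 1540 ± 23.4, 1540 ± 90.7 and 1460 ± 104. Camera called the list lower (adjusted p = 0.0143, 0.003 and 0.034; adjusted p = 0.74, 0.66 and 0.936 with an estimated correlation). Of the 24 ribosome biogenesis genes, 5, 6 and 5 fell and 2 rose in each group, and adjusted over the list alone 4, 6 and 3 fell and 2 rose. Of the 21 nucleotide synthesis genes, 6 fell in each group, also adjusted over the list alone, and 1 rose in Myc_KO; Uck2 went from 117 ± 9.49 to 48.9 ± 1.74, 43.7 ± 9.52 and 64.1 ± 10.7. Of the 16 genes of amino acid transport and one-carbon metabolism, 3, 4 and 2 fell and 0, 0 and 2 rose, or 2, 4 and 1 that fell and 0 that rose adjusted over the list alone; the glutamine transporter gene Slc1a5 went from 362 ± 20.8 to 179 ± 35.9, 184 ± 26.5 and 192 ± 21.1. Camera called the amino acid list in Max_KO (adjusted p = 0.0263; adjusted p = 0.66 with an estimated correlation) and not in the other 2 groups (0.187 and 0.482), and called neither ribosome biogenesis (0.0974, 0.129 and 0.292) nor nucleotide synthesis (0.252, 0.185 and 0.246) in any group with the described groups.

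These lists depended on the disputed libraries. With the undisputed libraries, 11 of 24 ribosome biogenesis genes, 8 of 21 nucleotide synthesis genes and 5 of 16 amino acid genes fell in Myc_KO, and camera called the 3 lists lower there (adjusted p = 0.000951, 0.0236 and 0.0272; adjusted p = 0.632, 0.632 and 0.547 with an estimated correlation). With groups from the titles, 13, 9 and 5 fell, and camera called them as well (adjusted p = 0.00168, 0.00894 and 0.0185; adjusted p = 0.468, 0.466 and 0.466 with an estimated correlation). In double_KO, 5 ribosome biogenesis genes rose and 2 fell with the undisputed libraries (median 0.02), and 5 rose and 4 fell under the titles (median -0.02). Of the Myc-induced genes, 12 of 22 fell in Myc_KO and 5 in double_KO with the undisputed libraries. The camera call of this list in double_KO was lost with the undisputed libraries (adjusted p = 0.246) and under the titles (adjusted p = 0.0793).

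Genes of the cell cycle and of cell survival moved in both directions. Pola1, a subunit of DNA polymerase alpha, rose from 45.1 ± 1.16 RPM to 80 ± 4.48, 80.6 ± 2.04 and 77.2 ± 6.85 in Myc_KO, Max_KO and double_KO, and Aurka, a mitotic kinase gene, fell from 84.3 ± 2.08 to 53.7 ± 1.22, 50.6 ± 2.28 and 58 ± 6. Bcl2, an inhibitor of apoptosis, rose from 61.8 ± 1.53 to 133 ± 12, 139 ± 0.192 and 120 ± 14.2, and Bcl2l11, which promotes apoptosis, fell from 139 ± 0.608 to 57.3 ± 3.09, 76.5 ± 12.7 and 69.5 ± 8.12. Of the 20 DNA replication genes, 5, 3 and 3 rose and 0, 2 and 1 fell; of the 15 mitosis genes, 1, 2 and 0 rose and 7, 4 and 5 fell. Of the 9 tested BCL2 family genes, 2 rose in each group and 2, 1 and 2 fell. Among the 16 CDK inhibitors and p53 targets, 1, 2 and 4 rose and 6, 8 and 6 fell, including Phlda3, from 25.3 ± 3.92 to 10.4 ± 0.218, 8.47 ± 0.873 and 9.87 ± 1.9. Adjusted over the list alone, these numbers were the same except that 7 mitosis genes fell in double_KO and that 5 CDK inhibitors and p53 targets rose and 7 fell in double_KO. Camera called the CDK inhibitors and p53 targets lower in Max_KO (adjusted p = 0.00588; adjusted p = 0.66 with an estimated correlation) and none of the other lists of this paragraph with the described groups. For mitosis in Myc_KO the adjusted p was 0.0517, and camera called it lower with the undisputed libraries (adjusted p = 0.0236; adjusted p = 0.547 with an estimated correlation) and under the titles (adjusted p = 0.0229; adjusted p = 0.466 with an estimated correlation).

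Several B cell identity genes rose in each knock-out group. Pax5, the factor that maintains B cell identity, went from 379 ± 4.67 RPM to 1070 ± 0.101 in Myc_KO, 1190 ± 302 in Max_KO and 1320 ± 94.3 in double_KO. Bach2, a repressor of plasma cell differentiation, went from 63.5 ± 5.9 to 169 ± 12.7, 200 ± 38.1 and 234 ± 17, and Ebf1 from 54.7 ± 0.445 to 135 ± 11.9, 135 ± 20 and 162 ± 23.8. Of the 21 mature B cell genes, 11, 10 and 12 rose and none fell, also adjusted over the list alone (medians 0.46, 0.38 and 0.48), and camera called the list higher (adjusted p = 0.000878, 0.00168 and 0.00117; adjusted p = 0.74, 0.66 and 0.906 with an estimated correlation). Atm, a DNA damage kinase, rose from 59.7 ± 1.94 to 387 ± 23.7, 322 ± 96.3 and 365 ± 10.3. Of the 16 class switch genes, 5, 3 and 4 rose and 6, 5 and 6 fell, and of the 18 NF-kB and IL-4 response genes 7, 6 and 4 rose and 2, 1 and 4 fell, with the same numbers adjusted over the list alone. Camera called neither list in any group. In double_KO the NF-kB and IL-4 list had a median of 0.06 while the test pointed lower (adjusted p = 0.988).

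Several plasma cell genes fell in Max_KO. Xbp1, a regulator of secretory cells, went from 737 ± 79.5 RPM to 403 ± 39.7 in Myc_KO, 267 ± 59.7 in Max_KO and 390 ± 37.8 in double_KO. Jchain, which links antibody multimers, fell to 36.4 ± 1.36 in Max_KO from 232 ± 31.9. Sdc1, the plasma cell marker CD138, rose in double_KO from 5.99 ± 0.0238 to 15.7 ± 1.13 (log2 change 1.39 ± 0.179, limma adjusted p = 0.000878; under the titles 1.01 and adjusted p = 0.052, with 0.000485 to 0.0643 over the alternatives). Of the 14 tested plasma cell genes, 4, 7 and 3 fell and 1, 0 and 3 rose, or 3, 7 and 3 and 0, 0 and 3 adjusted over the list alone (medians -0.26, -0.6 and -0.1). Camera called the list in Max_KO (adjusted p = 0.0012; adjusted p = 0.66 with an estimated correlation) and not in Myc_KO (0.131) or double_KO (0.876), where the mean of 0.02 had the opposite sign to the median. Among the 13 genes of the unfolded protein and stress responses, 2, 2 and 1 rose and 5, 4 and 3 fell, or 2, 2 and 1 and 6, 4 and 3 adjusted over the list alone, and Ddit4, a stress-induced gene, went from 158 ± 30.9 to 31.1 ± 8.38, 49.8 ± 24 and 29.6 ± 3.3. Of the 21 lysosome and autophagy genes, 4, 5 and 3 rose and 2, 3 and 1 fell, also adjusted over the list alone. Camera called neither list in any group.

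Interferon response genes rose in each knock-out group. Of the 15 genes, 13 rose in Myc_KO, 10 in Max_KO and 15 in double_KO, or 14, 10 and 15 adjusted over the list alone (medians 1.79, 1.53 and 2.34). Ifit1, an antiviral protein gene, went from 10 ± 0.252 RPM to 84.9 ± 19.9, 62.8 ± 24.9 and 70.8 ± 1.94. Camera called the list higher (adjusted p = 2.97e-06, 0.000301 and 1.43e-06; adjusted p = 0.74, 0.66 and 0.831 with an estimated correlation).

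Markers of other cell types were measured beside these groups. Of the 16 tested T and NK cell markers, 10, 9 and 12 rose and 1, 0 and 1 fell, or 12, 9 and 13 and 1, 0 and 1 adjusted over the list alone (medians 2.28, 1.58 and 2.25), and camera called the list higher (adjusted p = 0.000313, 0.00878 and 0.000862; adjusted p = 0.74, 0.66 and 0.888 with an estimated correlation). Cd8a was at 1.03 and 1.36 RPM in the control libraries and at 6.94 to 20.9 in the knock-out libraries, and Lck, a T cell kinase gene also detected in the controls, rose in Myc_KO from 36.2 ± 2.98 to 109 ± 5.04. The member that fell was Thy1, at 323 and 275 in the controls and 71.2 to 137 in the libraries labelled Myc_KO and double_KO. Of the 5 tested myeloid and dendritic markers, 3, 3 and 4 rose and 1 fell in each group, or 4, 3 and 4 and 1 adjusted over the list alone, without a camera call (adjusted p = 0.217, 0.371 and 0.216). Fry called these markers higher in each group (adjusted p = 0.00837, 0.026 and 0.00753). Adgre1, a macrophage receptor gene, rose from 1.31 ± 0.671 to 21.3 ± 8.26 in Myc_KO, and Cd68, a lysosomal protein of macrophages, fell from 11.4 ± 0.949 to 3.85 ± 0.763 in Max_KO; that call of Cd68 was lost without control replicate 1 (adjusted p = 0.072) and without Max_KO replicate 1 (adjusted p = 0.05), with 0.00085 to 0.072 over the alternatives. Of the 5 precursor B cell genes, 2, 0 and 1 rose and 2 fell in each group, or 2, 0 and 3 and 2 adjusted over the list alone, with medians (0.28, 0.19 and 0.81) above 0 and means (-0.66, -0.57 and -0.33) below it and no camera call. Fry called the precursor list lower in each group (adjusted p = 0.00837, 0.026 and 0.0474). The call in double_KO was lost with the replicate number as a block (fry adjusted p = 0.421). Germline, erythroid and stromal genes were too few for a set test: 2, 3 and 3 of 4 tested germline genes rose (3 in each group adjusted over the list alone), and Itga2b, the 1 erythroid and platelet marker tested, fell in Myc_KO and Max_KO. By its unadjusted p, which adjusting over a list of 1 gene leaves as it is, Itga2b fell in all 3 groups. Each call of a germline gene was lost without at least 1 library. Smc1b was lost in Myc_KO without control replicate 1, control replicate 2 or the library labelled Myc_KO replicate 1 (adjusted p = 0.064, 0.109 and 0.102). It was lost in Max_KO without Max_KO replicate 2 (0.0548), and in double_KO without control replicate 1, control replicate 2 or double_KO replicate 1 (0.0604, 0.0996 and 0.125). Tdrkh was lost without control replicate 1 in Myc_KO, Max_KO and double_KO (0.183, 0.0565 and 0.11), and without the library labelled Myc_KO replicate 1 (Myc_KO, 0.136) and double_KO replicate 1 (double_KO, 0.0886). Sycp1, called in Max_KO and double_KO, was lost in both without any 1 library except control replicate 1, with adjusted p of 0.119 and 0.121 without control replicate 2, 0.106 and 0.0669 without Max_KO replicate 1, 0.177 and 0.067 without Max_KO replicate 2, 0.0569 and 0.0556 without either Myc_KO library, 0.0583 and 0.0809 without double_KO replicate 1, and 0.0596 and 0.184 without the library labelled double_KO replicate 2. Over the alternatives adjusted p ranged from 0.0108 to 0.298, 0.00138 to 0.0548 and 0.00175 to 0.534 for Smc1b in Myc_KO, Max_KO and double_KO, from 0.0149 to 0.183, 0.00536 to 0.0565 and 0.00787 to 0.178 for Tdrkh, and from 0.00684 to 0.186 and 0.00622 to 0.473 for Sycp1 in Max_KO and double_KO. The call of Itga2b in Myc_KO was lost without control replicate 1, control replicate 2 or the library labelled Myc_KO replicate 1 (adjusted p = 0.0985, 0.0694 and 0.0566, with 0.00765 to 0.0985 over the alternatives), and that in Max_KO without control replicate 1, control replicate 2, Max_KO replicate 1, double_KO replicate 1 or the library labelled double_KO replicate 2 (adjusted p = 0.167, 0.12, 0.156, 0.0576 and 0.0586, with 0.0148 to 0.167). Pecam1, 1 of 2 stromal and endothelial markers, rose from 36.8 ± 4.46 to 106 ± 27.9 in Myc_KO and in the other groups, while the other marker fell in Max_KO when adjusted over the list alone.

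Changes were largely in the same direction across the knock-out groups. Called in the same direction were 3803 genes in Myc_KO and Max_KO, 4125 in Myc_KO and double_KO and 3935 in Max_KO and double_KO; 7, 0 and 8 were called in opposite directions. In all 3 groups 2065 genes rose, among them Pax5, Bach2 and Ccnd2, and 1428 fell, among them Rpl28; under the titles the numbers were 2155 and 1508, and 2029 and 1378 were called under both groupings. Independent lists of the same sizes would share 596 rising and 385 falling genes (Myc_KO and Max_KO), 649 and 437 (Myc_KO and double_KO) and 625 and 391 (Max_KO and double_KO), against 2223 and 1580, 2344 and 1781, and 2301 and 1634 observed. Unchanged groups simulated against the same controls shared 0.06 genes on average and at most 1 over 50 draws. Without changed genes almost none are called in such draws, so that this number is no measure for lists of the observed sizes. The draws also took the noise of each gene as independent of the others. Across genes, which are not independent replicates, Pearson's r of the log2 changes was 0.84, 0.87 and 0.86, against 0.5, 0.5 and 0.49 in the simulation, and the covariance was 0.679, 0.759 and 0.706 against 0.0558, 0.0557 and 0.0557. With a different control library for each of the 2 groups, a split chosen after seeing the data, the shared genes were 1751, 2081 and 1907, and 1849, 2047 and 1782 with the 2 control libraries exchanged. Independent lists of those sizes would share 295 to 361. The covariance was then 0.611 to 0.721. The undisputed libraries shared 3313, 2751 and 3180. Without control replicate 1 the shared genes were 1790, 2102 and 1836, without control replicate 2 they were 2218, 2473 and 2276, and without Max_KO replicate 2 those of Max_KO and double_KO were 2519. With the number series as a term, which only the Max_KO libraries inform, double_KO shared 330 genes with Myc_KO and 330 with Max_KO.

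Between Max_KO and Myc_KO, Myc was 2.09 ± 0.117 higher in Max_KO on the log2 scale (184 ± 11.2 against 43.6 ± 6.78 RPM; limma adjusted p = 0.000304). Trim12a and Trim30d, antiviral TRIM family genes on chromosome 7, were lower in Max_KO by log2 changes of -7.1 ± 0.364 and -7 ± 0.277 (limma adjusted p = 0.000227 and 5.58e-05, with 0.000112 to 0.085 and 2.58e-05 to 0.0363 over the alternatives), and Gvin1, an interferon-induced GTPase gene on the same chromosome, by -3.88 ± 0.245. Jchain was lower by -2.43 ± 0.275 (adjusted p = 0.0249), a call lost without control replicate 1, control replicate 2, Max_KO replicate 1 or Max_KO replicate 2 (adjusted p = 0.0743, 0.0734, 0.131 and 0.13), with 0.000498 to 0.165 over the alternatives. Limma called 13 genes, 4 higher and 9 lower in Max_KO, while 1415 had an unadjusted p under 0.05. The number was 515 (304 higher, 211 lower) with groups from the titles, 372 with the undisputed libraries, 77 without the library labelled Myc_KO replicate 1, and 6 without Myc_KO replicate 2. Pooling the 4 libraries that either label gives a Myc loss, a comparison that does not depend on the disputed labels, limma called 28 genes against Max_KO, 2 higher and 26 lower in Max_KO. Against the control the pooled libraries had 5749, 3116 higher and 2633 lower. Under the titles, Stag3, a cohesin subunit of meiotic cells, was higher in Max_KO by 4.54 (limma adjusted p = 4.37e-05; under the descriptions 2.73 ± 1.38 and adjusted p = 0.497), with 113 and 140 RPM in Max_KO against 4.86 and 6.07 in the 2 libraries titled Myc_KO. Camera with the preset correlation called 8 lists, among them the plasma cell programme lower in Max_KO (2 of 14 genes lower, 6 adjusted over the list alone; adjusted p = 0.000105; adjusted p = 0.694 with an estimated correlation).

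Between double_KO and Myc_KO, Sdc1 was at 16.5 and 14.9 RPM in the libraries labelled double_KO against 8.86 and 8.26 in those labelled Myc_KO, and Myc at 55.4 and 55.8 against 38.8 and 48.3. Limma called 0 genes, with 1318 at an unadjusted p under 0.05. Limma with voom weights also called 0. With groups from the titles the number was 57, of which 52 were higher in double_KO, and with the undisputed libraries it was 29; it was 1 without the library labelled Myc_KO replicate 1 and 3 without double_KO replicate 1. Under the titles Stag3 was higher by 3.94 (limma adjusted p = 0.000138, against 0.954 under the descriptions), the kinase gene Camk2a by 2.41 (adjusted p = 0.00337 against 0.978) and the phosphatase gene Ptprs by 2.32 (adjusted p = 0.00252 against 0.904), and Max was lower, with a log2 change of -1.12 (adjusted p = 0.0109 against 0.974). Camera called 1 list, the plasma cell programme, higher in double_KO (median 0.18, 0 of 14 genes called and 1 adjusted over the list alone; adjusted p = 0.00599; adjusted p = 0.964 with an estimated correlation). Without 1 library at a time the number of lists reached 12, without double_KO replicate 1.

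Between double_KO and Max_KO, Trim12a and Trim30d were higher in double_KO, by 6.17 and 5.85 on the log2 scale, and Myc was lower, by -1.73 ± 0.117. Jchain was at 261 and 260 RPM in the libraries labelled double_KO against 37.4 and 35.4 in Max_KO (log2 change 2.84 ± 0.275, limma adjusted p = 0.0116); the call was lost without Max_KO replicate 1, Max_KO replicate 2 or the library labelled double_KO replicate 2 (adjusted p = 0.108, 0.0511 and 0.0627), with 0.000146 to 0.11 over the alternatives. Limma called 26 genes, 25 higher and 1 lower, with 1146 at an unadjusted p under 0.05. The number was 5 with groups from the titles and 24 with the undisputed libraries, of which 11 were among the 26. It was 7 without either control library, 6 without Max_KO replicate 1, 16 without Max_KO replicate 2, 52 without the library labelled Myc_KO replicate 1, 42 without Myc_KO replicate 2, 16 without double_KO replicate 1, 8 without the library labelled double_KO replicate 2, and 6 with the number series as a term. Camera called 10 lists, led by the plasma cell programme (4 of 14 genes higher, 9 adjusted over the list alone; adjusted p = 1.91e-10; adjusted p = 0.425 with an estimated correlation).

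The last comparison asked whether the change in double_KO equals the sum of the changes in Myc_KO and Max_KO, as a contrast of the 4 groups on the log2 scale. Mt2 lay above the sum by 6.12 ± 0.717 and Muc1 by 4.55, and Iigp1 lay below it, at -6.23, as did Gzmb, at -4.57. Without control replicates 1 and 2 Iigp1 lay at -5.17 and -7.29, and without Myc_KO replicates 1 and 2 Gzmb lay at -5.19 and -3.95. Gzmb rose 49.8-fold in Myc_KO, 22.2-fold in Max_KO and 46.6-fold in double_KO. Rpl28 was at 2140 ± 154 RPM in the controls and at 796 ± 30.5, 889 ± 61.3 and 797 ± 90.9 in the knock-out groups, which left its change in double_KO above the sum by 1.26 ± 0.166. Limma called 2595 genes, 1103 above the sum and 1492 below. For 2593 of them the difference went against the summed change. The interaction and the sum share libraries with opposite signs, which by itself favours that direction. In 50 draws simulated with additive changes, 0.12 genes were called on average and 2 at most, and 68.7% of those at an unadjusted p under 0.05 went against the sum. Without departures from the sum almost none are called in such draws by construction. The draws also took the noise of each gene as independent of the others, so that they do not measure noise shared between genes. Across genes, the slope of the double_KO change on the sum was 0.49, against 0.93 in the simulation. All 3 changes share the 2 control libraries, and the number was 833 without control replicate 1, 1119 without control replicate 2 and 1404 without double_KO replicate 1. With groups from the titles it was 3404, and with the undisputed libraries 2341. Camera called 13 lists, with 27 of 30 ribosomal protein genes above the sum (30 adjusted over the list alone; adjusted p = 4.2e-16; adjusted p = 0.672 with an estimated correlation).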

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

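The tests named in this part were chosen only after the results they measure were seen; the interaction was planned.

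The interaction called 2595 genes by limma, with 4535 at an unadjusted p under 0.05, and is listed here because it is a test of whether the effect of losing Max differs between groups with and without Myc. The number was 833 without control replicate 1, 1119 without control replicate 2 and 1404 without double_KO replicate 1, all 3 changes share the 2 controls, and Max stood at 59.8 RPM in the library labelled double_KO replicate 2, above both controls.

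Max and other transcripts disagreed with the descriptions of 2 libraries. Max in the library labelled Myc_KO replicate 1 was 0.52 of the control mean, which argues against correct descriptions with a remainder of Max in the library labelled double_KO replicate 2 as the whole account. Over 264 genes chosen because they differed between Myc_KO replicate 2 and Max_KO, the library labelled Myc_KO replicate 1 lay nearer Max_KO than the library labelled double_KO replicate 2 did in 74.6% of genes, and exchanged descriptions are a candidate explanation. The median positions, 0.62, 0.26 and 0.7 for double_KO replicate 1, do not measure loss of Max, since the controls lay at 0.78 and 0.79, and show only that the library labelled double_KO replicate 2 lay nearest Myc_KO replicate 2. In the libraries labelled replicate 1 of Myc_KO and double_KO, Max was at 28.6 and 31.2 RPM, against 70.5 and 59.8 in replicate 2. Stag3 was at 74 and 93.4 against 4.86 and 6.07 in the same order. Mnt was at 67.7 and 78.2 against 22.8 and 38.1, and Ptprs at 62.1 and 53.8 against 13.7 and 9.75. These pairs follow the titles and cross their number series, though Stag3 and Ptprs were named because the title groups called them. Other levels point the other way, in the libraries labelled Myc_KO replicates 1 and 2 against those labelled double_KO. Gvin1 was at 863 and 1280 RPM against 327 and 476, and Trim12a at 82.8 and 91.4 against 41 and 50.9. Trim30d was at 77.7 and 90.6 against 30.8 and 46.5, and Trim34b at 1.1 and 0.836 against 8.1 and 6.93. Sdc1 was at 8.86 and 8.26 against 16.5 and 14.9. This pairing follows the descriptions and equally the number series of the titles. Gvin1, Trim12a and Trim30d all lie on chromosome 7, so that they may not be independent of each other. The 2 Max_KO libraries, 1 of each number series, were alike for Gvin1 (67.7 and 75.5), Sdc1 (2.97 and 3.04) and Trim34b (9.56 and 13.9).

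T and NK cell transcripts were higher in the knock-out libraries. The median change of the T and NK list was at least 1.64 in each group under quantile and same-total scaling, which argues against scaling as the cause. A larger share of T or NK cells may contribute: 14 T cell receptor genes, listed after some of their values were seen, had a median change of 2.83 against the controls, although mature B cells had been sorted. Levels stayed low for the receptor genes, at most 3.36 RPM for Cd3e and 6.54 for Trbc2, while Gzmb reached 127, and Thy1 and Cd68 were lower, at 71.2 to 228 and 3.23 to 6.34 against 275 to 323 and 10.7 to 12 in the controls. Other cells and a change within B cells cannot be told apart, since no library measures the cell types and losing Myc or Max goes with the change in every group.

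Trim genes of chromosome 7 were nearly silent in both Max_KO libraries. In the libraries called double_KO by either label, Trim12a, Trim30d and Trim5 lay at least 3.29 on the log2 scale above the higher Max_KO library, which argues against loss of Max as the whole cause, although Max itself was higher in those libraries than in Max_KO. Of the 6 genes called over 4-fold lower in Max_KO than in both other knock-out groups, 4 lie within 5 Mb (101970014 to 106970014) that hold 38 of the 12467 tested genes (Fisher exact p = 1.1e-09), and a strain variant of this region is a candidate explanation. The region was chosen from the genes that show the pattern, so that the p-value does not decide it. Strain and loss of Max cannot be told apart within Max_KO, and reads shared between Trim copies were not examined; Trim34b, in the same family, was at 9.56 and 13.9 in Max_KO against 0.281 and 3.24 in the controls.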

How the results depend on the processing

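Alternatives with voom weights, a pseudocount of 1, the number series of the titles, and pooled or subset libraries were chosen after seeing the data. A count test was not run, since the estimated reads are not whole. Over the 321 named gene results and all alternatives, 8141 values kept their direction and side of the threshold. Of the others, 613 kept the direction but lost the call, 43 gained it and 13 reversed. With the number series as a term 97 lost it, and 10 lost it with that term and groups from the titles. Depth of 14.88 to 17.91 M reads limits genes near the floor. Where a group keeps 1 library, that library is assumed to vary like the others. The cause was not tested for any change below, except that stricter thresholds call fewer genes by construction.

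Called genes with 1 library left out ranged from 2662 to 5198 (Myc_KO), 2250 to 4884 (Max_KO), 2753 to 5372 (double_KO), 6 to 77 (Max_KO against Myc_KO), 0 to 3 (double_KO against Myc_KO), 6 to 52 (double_KO against Max_KO) and 833 to 2175 (interaction). Genes called in the same direction ranged from 1790 to 3696 (Myc_KO and Max_KO), 2102 to 4178 (Myc_KO and double_KO) and 1836 to 4028 (Max_KO and double_KO). Lists ranged from 8 to 11, 11 to 13, 7 to 13, 2 to 12, 1 to 12, 9 to 15 and 9 to 16 in the order of the comparisons.

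At an adjusted p threshold of 0.01, called genes were 2853, 2532 and 2911 for Myc_KO, Max_KO and double_KO, 5 for Max_KO against Myc_KO, 4 for double_KO against Max_KO and 734 for the interaction, and shared genes were 2008, 2246 and 2033. With at least 2-fold change they were 1762, 1486, 1844 and, for the interaction, 1094, and shared genes 1051, 1308 and 1102. With the number series as a term, Max_KO had 2920, double_KO 334 and double_KO against Max_KO 6. The overlaps of double_KO with Myc_KO and with Max_KO were 330 and 330. Under the descriptions only Max_KO has a library in each series, so that these numbers do not measure an effect of the series. Within the 30s series Max_KO had 2916.

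With groups from the titles, Max_KO against Myc_KO had 515, double_KO against Myc_KO 57 and double_KO against Max_KO 5, and the lists called were 15, 17 and 16; adding the number series gave 1308, 291 and, for the interaction, 4634. Without the 2 disputed libraries the first 2 were 372 and 29, with 14 lists for double_KO against Myc_KO. With only the groups compared they were 5 and 4, and 9 for double_KO against Max_KO. For double_KO against Max_KO, a pseudocount of 5 gave 7, quantile normalization 10, eBayes without a trend 6 (interaction 1704) and voom weights 4, which also gave 4 for Max_KO against Myc_KO. Camera with an estimated correlation called 0 lists in each of the 7 comparisons. Fry called 0 for Max_KO against Myc_KO, 0 for double_KO against Myc_KO, 1 for double_KO against Max_KO and 3 for the interaction. Against the control fry called several lists in Myc_KO, Max_KO and double_KO. Among them were the ribosomal proteins (fry adjusted p = 0.00837, 0.0168 and 0.00753), mitochondrial transcripts (0.0153, 0.0271 and 0.0147) and interferon response (0.00952, 0.026 and 0.012). It called neither glycolysis (0.0789, 0.194 and 0.0939) nor the Myc-induced genes (0.364, 0.2 and 0.472).

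With the replicate number as a block, Max_KO against Myc_KO had 45 genes and double_KO against Max_KO 87, and 14 of the 16 glycolysis genes were lower in Max_KO. Camera then called ribosome biogenesis (adjusted p = 0.0368, and 0.754 with an estimated correlation) and mitosis (adjusted p = 0.0369, and 0.754 with an estimated correlation) lower in Myc_KO. Over all genes the replicate numbers were not clearly found to pair the libraries, which does not exclude a shift shared by some genes.

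Reversed values, none past the threshold as reported, were as follows. Max in Myc_KO was 0.25 with groups from the titles, 0.36 without the 2 disputed libraries, 0.28 with titles and number series, and 0.36 without the library labelled Myc_KO replicate 1. Mxd3 in Myc_KO was -0.12, -0.02, -0.07 and -0.12 without the disputed libraries, with titles and number series, without control replicate 1 and without the library labelled Myc_KO replicate 1. Mnt in Myc_KO was -0.15 without the disputed libraries and without the library labelled Myc_KO replicate 1. With 1 library left out in turn, Max in Myc_KO ranged from -0.93 to 0.36, Mxd3 in Myc_KO from -0.12 to 0.21, Mnt in Myc_KO from -0.15 to 1.42, Mycl in Max_KO from -0.27 to 0.65, Max in double_KO from -0.81 to 0.13 and Mxd3 in double_KO from -0.01 to 0.21. Mycl in Max_KO was -0.27 and Mxd3 in double_KO -0.01 without control replicate 1, and Max in double_KO was 0.13 without double_KO replicate 1.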

Other observations

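The tests named in this part were chosen only after the results they measure were seen.

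Targets of the hypoxia-inducible factors, which respond to low oxygen, were in part lower in the knock-out groups. Bnip3, a mitophagy receptor, was at 191 and 190 RPM in the controls, at 138 and 48.5 in Max_KO, at 46.7 and 13.8 in the libraries labelled Myc_KO and at 43.8 and 11.7 in those labelled double_KO. Vegfa, a growth factor of blood vessels, was at 119 and 137, then 50.9 and 15.3, 26.7 and 23.3, and 28.9 and 20.8. Of the same list, Adm, Pfkfb4, Pfkfb3, Car9 and Ankrd37 were not below both controls in every knock-out library: Adm was at 11.2 to 29 against 16.7 and 19, Pfkfb4 at 12.1 to 16.5 against 15.7 and 14.9, and Car9 at 1.23 to 1.89 against 1.25 and 1.2. Pfkfb3 and Ankrd37 were at 58.9 and 56.7 in Max_KO replicate 1, above both controls (48.9 and 56.7, and 47.5 and 53.4). Of 16 genes, 10 fell in Myc_KO, 8 in Max_KO and 12 in double_KO (medians -1.87, -1.22 and -1.92), and with groups from the titles 13, 9 and 10.

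A lower response of these factors may be part of the change: the highest adjusted p by camera over the 3 groups was 0.000413 with the preset correlation, and p was 0.21, 0.263 and 0.19 with an estimated correlation. The list was written after values of its members and of other candidates had been seen, and Ak4, Egln3, Ddit4 and Selenbp1 were left out of it, so that the test does not decide. Glycolysis genes share regulation by these factors, and the labels give no oxygen level for the cultures.

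Germline genes were considered as a second group, since Stag3 stood at 113 and 140 RPM in Max_KO, 74 in the library labelled Myc_KO replicate 1 and 93.4 in double_KO replicate 1, against 22.2 and 19.4 in the controls and 4.86 and 6.07 in Myc_KO replicate 2 and the library labelled double_KO replicate 2. A loss of repression that needs Max is a candidate explanation. With groups from the titles, the 4 tested germline genes had a median log2 difference of 0.21 between double_KO and Myc_KO, under the value a shared rise would need, but several of the 4 lie near the floor and too few were tested to decide. Smc1b, of that list, was at 1.82 in the library labelled Myc_KO replicate 1 and 2.88 in double_KO replicate 1 against 0.751 in Myc_KO replicate 2 and 0.508 in the library labelled double_KO replicate 2. Outside the list and chosen after their values were seen, Rnf17 was at 3.33 and 4.8 against 0.751 and 0.775, and Tcam1 at 6.01 and 5.24 against 1.01 and 1.15, in the same libraries.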
